A study of Mus musculus with 192 samples.

How the data were processed

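Single R1 mouse ES cells were processed on 1 microfluidic chip, per the labels' protocols. Cells were separated from feeders by settling, depleted of dead and early apoptotic cells with annexin V beads, and frozen. After thawing they were lysed with a spike-in mix of synthetic RNAs, reverse transcribed with template switching, amplified by 21 cycles of PCR and barcoded by tagmentation. Per the series design, the same libraries were sequenced again after 9 further cycles.

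The values used were molecule counts per feature and cell barcode, as deposited by the authors and per the file headers. The submitters' processing notes name Bowtie and the mouse build mm10 (GRCm38), with no version. Per the file headers, reads with several matches were assigned to their most 5' exonic match and are included in the counts, and repeats were grouped by type over both strands. The table had 25914 features: 24264 genes, 96 spike-ins and 1554 repeat types. The total of each feature equalled the sum of its wells in all of them. Of the genes, 14304 had a molecule in any well. Multiply matched reads gave 26.7% of gene molecules. Among 118 named genes, 29 had under 50% of their molecules from unique reads and are uncertain: mt-Co1, mt-Co3, Ftl1, Gm6251, BC002163_loc2, Gm10094, Klf4, Hmgb2, Ccnb1, Hsp90aa1, Hspa8, Hspb1, Hmgb1, Hdac1, Ppia, Eef1a1, Actg1, Rplp0, Rps29, Rplp1, Rpl32, Rps4x, Rpl6, Rpl23a, mt-Co2, mt-Tc, mt-Atp6, Pou5f1 and Pgk1.

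Wells with at least 5000 gene molecules were kept, leaving out spike-ins and repeats, and all 96 wells passed. The table marks no wells as used by the authors, and the images of the chambers that the labels' protocols mention were not used here, so a chamber without an intact cell was not recognised as such. No doublet caller was run. For clustering, the 500 genes with the largest ratio of observed to technical squared CV and a mean of at least 0.5 were taken as log2(molecules per 10000 + 1), and 10 principal components were clustered by Ward's method. From 2 to 6 clusters were tried, and 4 had the highest mean silhouette (0.477, against 0.473 for 3). Clusters were named only from fixed markers. Leading genes were ranked by fold of mean level with 0.1 added to both levels, among genes with a level of at least 1.

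The technical fit was squared CV = a/mean + b over spike-ins with a mean of at least 0.1, a gamma model with identity link, after division by the spike-in total of the well. Gene counts were divided by the cell's total of gene molecules relative to the mean total. A gene counted as above technical noise where its mean was at least 1 and its squared CV at least 2 times the fit, with all cells and again without its highest cell. Intervals of ratios came from 1000 resamplings of cells with the fit held fixed, and cover the sampling of cells of this culture only. The 20 gene lists, 30 gene pairs, tests and most alternatives were fixed before the data were examined. List medians and correlations of log2(value + 1) were set against 10000 random lists or pairs matched on mean level in 20 bins. Counting the lists and pairs in the highest 2.5%, the limit of 4 times the median for outlying spike-in totals, the division of wells into ranges and the use of 1000 random lists in alternatives were chosen after the data were seen. L1 and B1 to B4 repeats were grouped by how their names begin, also chosen after the data were seen, because the fixed name patterns took in other repeats and missed many L1 types. By the fixed patterns, L1 made up 7.14% of repeat molecules with 30 of 36 types above technical noise, and B1 to B4 elements 53.3% with 17 of 27. Because 1 culture is 1 sample, no p-value or standard error was computed from cells.

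The genes named followed a rule fixed with the lists: the 10 largest ratios among genes above technical noise, the 5 highest means, the 5 lowest ratios among means of at least 20, from each list with at least 3 measured genes the 4 highest means and up to 4 of the largest ratios above technical noise, and both genes of each fixed pair with means of at least 1. Dnmt3a and the genes leading a cluster, a well or a correlation were named in addition. Of the named genes, 68 were above technical noise. Coordinates are those of GENCODE M21 on GRCm38 for symbols found in it, which held for 20764 genes (85.6%).

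The noise rule was tested on simulated data with 9467 genes and the fitted technical noise. Of 100 genes given an added CV of 1, 83% were recovered, and of 100 given 0.5, 24%, or 91.3% where the mean was at least 20. A spike-in coefficient of 3.33 was simulated and 3.91 recovered. A simulated list with a shared factor had a median rho of 0.514, above all random lists.

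Alternatives changed the wells kept, the normalization (spike-in total, none, thinning, scran pooled size factors), the thresholds and the class of wells. Thinned counts were compared with the fit of the full spike-in counts. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3 and scran 1.30.0. A comparison of libraries with and without additional PCR, planned with edgeR, was not made because each column serves both.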

Results

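The series measured RNA molecules in 96 chambers of a microfluidic chip loaded with single cells of R1, a mouse embryonic stem (ES) cell line grown on irradiated feeder fibroblasts. Cells were lysed together with spike-in RNAs and amplified by 21 cycles of PCR. The same libraries were sequenced as made and after 9 further cycles. The deposited table of molecule counts holds 1 column per chamber (well), so each column belongs to both library forms and the effect of additional PCR was not analysed here. All cells came from one culture, which makes them a single sample. Spreads below are spreads between cells or wells, and no p-value was computed.

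Wells held a median of 54192.5 gene molecules, from 8774 to 573648, and a median of 5630 detected genes, from 2617 to 12286. Totals fell into separate ranges: 45 wells held at most 35543 gene molecules and 51 held at least 51390. Spike-ins gave a median of 6998.5 molecules per well. Wells C03 (36465) and H03 (55740) held far more, and well H12 (926) far fewer. Mitochondrially encoded RNA made up a median of 15.4% of gene molecules.

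The wells formed 4 clusters, of which cluster 1 had the highest summed level of fixed ES cell markers. Cluster 1 held 41 wells (42.7%, exact binomial 95% interval 32.7% to 53.2%, counting error only). The median summed level of the 13 markers, all detected in every cluster, was 114 molecules per 10000 gene molecules there. It was 55.1 in cluster 2, 29.2 in cluster 3 and 30.5 in the only well of cluster 4. Dppa5a, an RNA-binding protein of pluripotent cells, had median levels of 92.2, 36.3, 19.8 and 22.2 in clusters 1 to 4. Utf1, a chromatin-bound factor of pluripotent cells, had 2.49 in cluster 1 and 0.859 in cluster 2, and Pou5f1 had 1.95 and 0.966. The sum was mostly Dppa5a, and some markers went the other way, with Zfp42 at 3.19 in cluster 1 and 5.63 in cluster 2, Sox2 at 0.672 and 1.03, and Nanog at 0.548 and 0.617. By fold over the other wells, cluster 1 was led by 8 copies of the small 4.5S RNA, the growth factor gene Gdf3 and Snurf. It was called ES cell-like and was used for all results on variation below.

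Cluster 2 held 45 wells with a median of 22949 gene molecules. They were the wells of the lower range apart from H12, which was ES cell-like, plus H08 with 52812. Small nucleolar RNAs (Snora75, Snord100, Snord17, Snord68), the microRNA gene Mir5109 and Larp1 were among its leading genes. Snora75 had a mean level of 9.02 per 10000 in cluster 2 and 1.16 in the other wells. Mitochondrial RNA made up a median of 29.1% of gene molecules, against 10.4% in cluster 1. Glycolysis genes had a median summed level of 59.4 per 10000 against 115, and ribosomal protein genes 903 against 1543. The cluster was left without a cell type name.

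Cluster 3 held 9 wells with a median of 109945 gene molecules. It was led by Igf2, a fetal growth factor, by the epithelial keratins Krt8, Krt18 and Krt19, with Anxa1, Anxa5, Tagln and S100a6 among the other leading genes. Krt8 had a median of 21.1 molecules per 10000 in cluster 3 and 1.23 in cluster 1, and Krt18 had 23.2 and 1.36. The leading genes held markers of both trophectoderm and feeder fibroblasts, so the cluster was not named. Cdx2, a trophectoderm transcription factor, was detected in 3 of its wells. Well E02 alone formed cluster 4, led by matrix and adhesion genes such as Thbs2, Cd44, Timp2, Bgn and Tnc. Feeder fibroblast markers summed to 123 per 10000 in E02, against a median of 8.32 in cluster 1 and of 41.8 in cluster 3, where the highest well had 185. No doublet caller was run on so few cells, and no well was removed as a doublet.

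**Figure D1:**
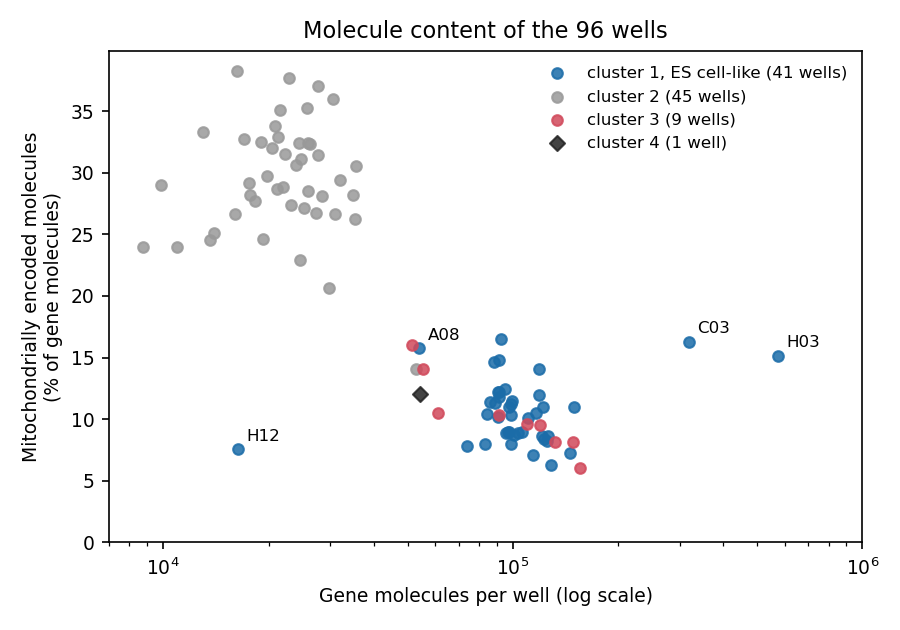
Each point is 1 of the 96 wells, with gene molecules per well on a log axis against the percentage of them that was mitochondrially encoded, coloured by cluster. Cluster 2 has a median of 22949 gene molecules and 29.1% mitochondrial RNA, and the ES cell-like wells have 98750 and 10.4%.

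Spike-ins set the level of technical variation, since each chamber received the same solution. Of 96 spike-ins, 75 gave a molecule and 62 entered the fit. Their squared coefficient of variation (CV) over all wells followed 3.33/mean + 0.009705, where independent single counts would give 1/mean. The median CV was 312% for 16 spike-ins with a mean from 0.1 to 1 molecule, 110.5% for 24 from 1 to 10, 27.6% for 13 from 10 to 100, and 12.4% for 6 from 100 to 1000. The fitted limit at high levels was 9.85%.

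The genes that varied most beyond the spike-ins among ES cell-like wells had unlike functions. The noise ratio is a gene's squared CV over 41 cells divided by the spike-in fit at its mean. Mt1 and Mt2, which encode metal-binding metallothioneins, had ratios of 40.98 (95% interval over resampled cells 8.23 to 60.2) and 20.5 (3.88 to 30.98). Trh, which encodes thyrotropin-releasing hormone, had 40.3 (11.6 to 54.2), with a mean of 64.9 ± 102 normalized molecules (SD over cells). Zfp42, also called Rex1 and a marker of the naive state, had 23.4 (16.3 to 28.5) with 100.2 ± 100.4 molecules. Dppa5a had 20.5 (12.5 to 28.3) with 964 ± 501. Malat1, a nuclear noncoding RNA, had 18.4 (10.8 to 25.7), Lefty1, a Nodal antagonist, had 17.7 (10.1 to 23.96), and Sfn, the 14-3-3 sigma gene, had 25.9 (4.45 to 41.5). Without the highest cell, the ratio of Sfn became 10.5 and that of Mt1 24.8.

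The other 2 of the 10 largest ratios rested mainly on single cells. Dqx1, a helicase-like gene, had 413 normalized molecules in well H04 and 34.7 in the next cell, and its ratio of 87.1 became 3.09 without that cell. Fst, which encodes the activin inhibitor follistatin, had 108 in well D01 and 25.8 in the next cell, with a ratio of 15.8 that became 2.99. Intervals over resampled cells were 0.941 to 99.85 for Dqx1 and 0.663 to 23.4 for Fst. In total 308 of 7717 genes with a mean of at least 1 molecule (3.99%) had a ratio of at least 2 both with all cells and without the highest cell. In simulated counts with technical noise only, 5 of 7406 genes met this rule. The median ratio over all tested genes was 1.26, against 0.967 in these simulated counts, so real genes as a whole lay higher. The simulation held only the fitted spike-in noise and does not cover other technical variation of genes. The number depended on the normalization: it was 622 after division by the spike-in total and 1197 with none. Thinning to 84541 gene molecules per cell, set against the fit of full counts, left out wells A03, A08, B10 and H12 and gave 120. Main values were scaled to a mean of 117605 gene molecules, so thinning lowered gene means and raised the fitted technical level. Some loss of calls can follow from this alone. Without thinning, the same cells gave 295, and Fbxo15, Lgals1, Mdm2, Dnmt3l, Jarid2 and Cdkn1c lost the call among the named genes. Of the 68 named genes above technical noise, those that lost the call after thinning were Dqx1, Fst, Nanog, Klf2, Fbxo15, Lefty2, Lgals1, S100a6, Ctgf, Tagln, Slbp, Ccnb1, Hsp90aa1, Fos, Junb, Jun, Dusp1, Mdm2, Ldha, Tpi1, Slc2a3, Tet1, Dnmt3l, Jarid2, Grb10, Cdkn1c, Rpl23a and Id1. Over all wells they were Dqx1, Nanog, Klf2, Tcl1, Dnmt3b, Id3, Lefty2, Ctgf, Slbp, Hmgb2, Ube2c, Hspb1, Fos, Junb, Jun, Dusp1, Mdm2, Ldha, Dnmt3l, Jarid2, Grb10, Cdkn1c, Rps15, Rpl6 and Id1.

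**Figure D2:**
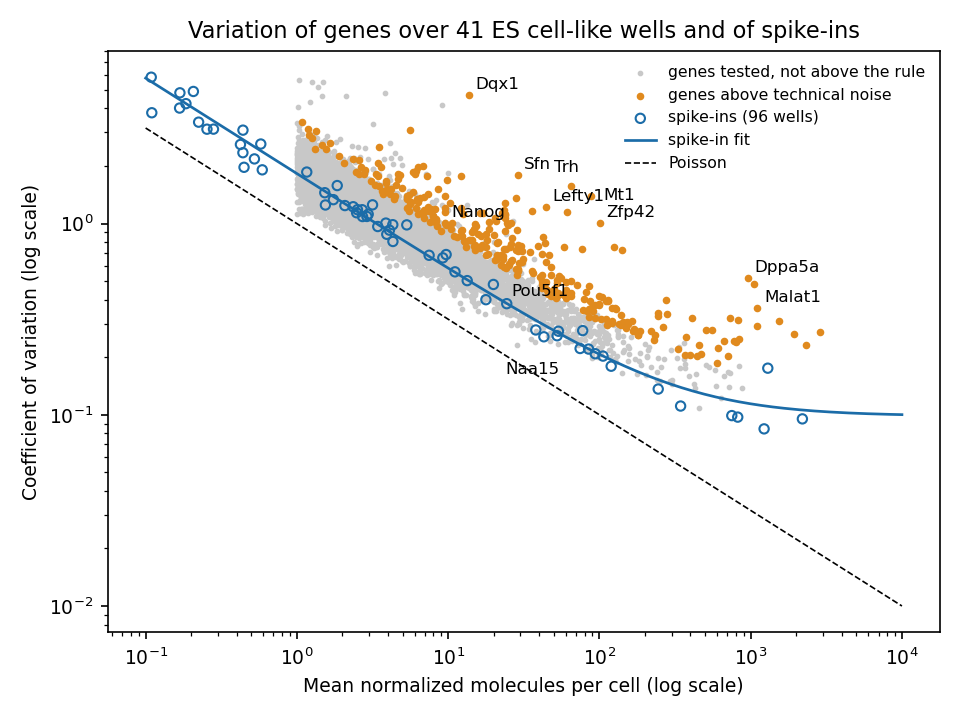
Each small point is the CV of a gene with a mean of at least 1 normalized molecule in the ES cell-like wells (308 above technical noise in orange), open circles are spike-ins over all wells, and both axes are logarithmic. The solid line is the square root of the spike-in fit and the dashed line Poisson counting, with Pou5f1 (ratio 1.005) on the fit and Zfp42 (23.4) far above it.

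On GRCm38, Dqx1 lies on chromosome 6 from 83057844 to 83067318, and Trh on chromosome 6 from 92242061 to 92244650. Mt1 lies on chromosome 8 from 94179082 to 94180327, Mt2 on chromosome 8 from 94172664 to 94173568, and Zfp42 on chromosome 8 from 43295063 to 43306980. Sfn lies on chromosome 4 from 133600556 to 133602168, and Dppa5a on chromosome 9 from 78367052 to 78368177. Malat1 lies on chromosome 19 from 5795690 to 5802672, Lefty1 on chromosome 1 from 180935022 to 180938400, and Fst on chromosome 13 from 114452290 to 114458951. Zfp42 had 59.3% of its molecules from uniquely mapped reads, Sfn 84.6% and Dppa5a 87.5%, while the other 7 genes had over 99%.

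The most abundant genes were Rn45s, the ribosomal RNA precursor, at 2879.7 ± 781 molecules, mt-Rnr2 at 2331 ± 539, mt-Co1 at 1934 ± 515, mt-Co3 at 1534 ± 474 and Ftl1, the ferritin light chain, at 1097 ± 396. Unique reads gave 0% of the molecules of mt-Co3, 1.68% of those of Ftl1 and 28.5% of those of mt-Co1, so these levels are uncertain and can hold molecules of near-identical copies. Among genes with a mean of at least 20, the lowest ratios belonged to Naa15, an N-terminal acetyltransferase subunit (0.433), Gm6251 (0.592), the splicing regulator Ptbp1 (0.598), the second locus of BC002163 (0.636) and Gm10094 (0.672). Gm6251 (49.6% unique), BC002163 (0%) and Gm10094 (0%) are uncertain for the same reason.

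Core pluripotency factors differed in how far they exceeded the spike-ins. Pou5f1, which encodes Oct4, varied no more than spike-ins, with 23.8 ± 9.23 molecules and a ratio of 1.005 (0.664 to 1.34), although 42.2% of its molecules came from unique reads. Sox2 (10.5 ± 9.097 molecules, ratio 2.31, 1.84 without its highest cell) and Utf1 (31.9 ± 13.6, ratio 1.59) were not above technical noise. Of 14 measured genes of the list, 4 were above it: Dppa5a, the Nodal co-receptor gene Tdgf1 (3.97), Gdf3 (3.73) and Nanog (2.82). Nanog had 9.53 ± 9.59 molecules and lost its call without wells C03, H03 and H12. The list's median ratio of 2.21 lay at the 99.9th percentile of 10000 random lists matched on mean level, and at the 71.7th with no normalization.

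The fixed naive-state and primed-state lists held strongly varying genes. Of 12 measured naive genes, 4 were above technical noise, namely Zfp42, the F-box gene Fbxo15 (8.18), Tcl1, an activator of Akt (4.52), and Klf2, a Krüppel-like factor (2.83). Intervals over resampled cells reached below 2 for Fbxo15 (0.716 to 11.4), Tcl1 (1.65 to 6.46) and Klf2 (1.07 to 4.18), but not for Zfp42. Klf4 (2.14, 38.7% unique and so uncertain) and Esrrb (2.5996) fell under 2 without their highest cell, and Esrrb was at 0 in 11 cells. Of 13 measured genes of the primed-state list, 8 were above technical noise. These were Lefty1, Lefty2 (6.08), the kinase gene Pim2 (5.55), Id2 (5.18), Id3 (4.67), Id1 (3.59) and the DNA methyltransferase genes Dnmt3b (4.17) and Dnmt3a (2.68). Intervals of Lefty2, Id2, Id1 and Dnmt3b reached below 2, and those of Lefty1, Pim2 and Id3 did not. Id genes encode inhibitors of basic helix-loop-helix factors. Otx2 of the primed list (2.2, and 1.02 without its highest cell) was not above technical noise. Whether the called genes mark a primed state in these cells was not tested. The median ratios of 2.33 for the naive list and 3.59 for the primed list lay above all random lists.

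**Figure D3:**
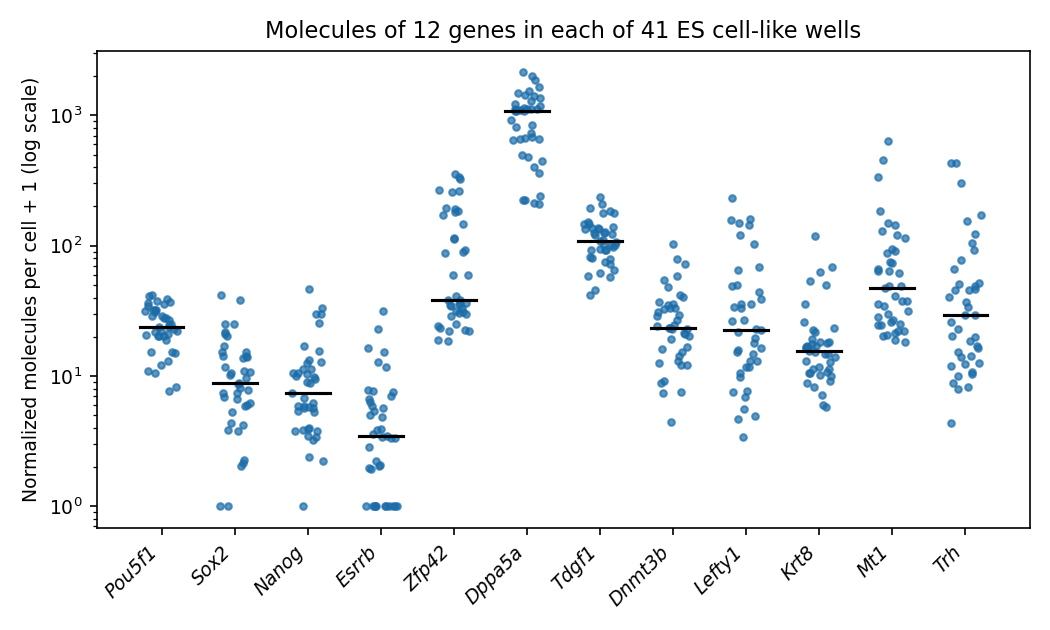
Normalized molecules plus 1 of 12 genes on a log axis, with 1 point for each of the 41 ES cell-like wells. Pou5f1 runs from 6.65 to 41.01, Tdgf1 from 41.2 to 237, Zfp42 from 17.6 to 354 and Trh from 3.33 to 434.

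Genes of other lineages and of feeder fibroblasts also varied within the ES cell-like wells. The keratin genes Krt8 (20.7 ± 21.3 molecules, ratio 6.24) and Krt18 (23.8 ± 21.9, ratio 5.65) were above technical noise among 4 measured trophectoderm genes, and both were highest in well H05. Among 12 measured feeder genes, 4 were above: Ctgf, a matricellular protein (5.42), Lgals1, galectin-1 (4.7001), S100a6, a calcium-binding protein (4.24), and Tagln, an actin-binding protein (3.66). These ratios leaned on single cells: without the highest cell they were 3.36 for Krt8, 3.11 for Krt18, 2.14 for Ctgf and 2.01 for Lgals1, and Krt19 went from 5.16 to 1.45 and Serpinh1 from 2.68 to 1.32. Krt18, Lgals1 and S100a6 lost their calls without wells C03, H03 and H12. Fst was the only gene above technical noise of 3 measured primitive endoderm genes. With all cells, median ratios were 5.403, 3.95 and 2.68 for trophectoderm, feeder and primitive endoderm lists, at the 99.98th, 100th and 99.5th percentiles. The neural, mesendoderm and 2-cell-like lists had 2 measured genes each and were left out.

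Immediate early and stress genes had 8 of 20 measured genes above technical noise, with a median ratio of 2.36 above all random lists. The transcription factor genes Junb (6.01), Jun (4.85) and Fos (3.501), the phosphatase gene Dusp1 (4.53) and the chaperone genes Hsp90aa1 (3.13) and Hspb1 (2.59) were among them. Without the highest cell Junb was at 2.62 and Dusp1 at 2.09, and Junb, Jun, Fos and Dusp1 lost the call both after thinning and over all wells. Among G2 and M phase genes 9 of 30 were above, including Ube2c (3.55), Hmgb2 (2.91), the cyclin gene Ccnb1 (2.75) and Top2a (2.74), but the list median of 1.54 lay at the 76.4th percentile. Among 25 G1 and S phase genes only Slbp, which binds histone mRNA, was above (3.17), with a median of 1.63 at the 94.6th percentile. Pcna (1.91), Mcm7 (1.62) and Tyms (1.93) were not above it. Hsp90aa1 (10.3% unique), Hspb1 (13.6%), Ccnb1 (13.1%) and Hmgb2 (42.8%) are uncertain because of shared reads.

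Metabolic and p53 lists also held genes above technical noise. Of 19 measured glycolysis and hypoxia genes, 6 were above technical noise, including Gapdh (4.85), Tpi1 (2.82), the glucose transporter gene Slc2a3 (2.74) and Ldha (2.46). Of 17 cholesterol synthesis genes only the sterol oxidase gene Sc4mol was above (4.15). Of 14 p53 and apoptosis genes only Mdm2, the p53 ubiquitin ligase gene, was above (6.26, 2.37 without well A03), and it lost the call after thinning and over all wells, with Bax at 1.68 and Trp53 at 1.04. Medians were 1.84, 1.72 and 1.68, at the 94.99th, 99.8th and 98.5th percentiles. The glycolysis list entered the highest 2.5% with the spike-in total (97.6th) and after thinning (97.9th). The cholesterol list left it after thinning (80.8th), with the spike-in total (89.1th) and over all wells (87.3th), and the p53 list with scran (94.5th), the spike-in total (96.5th) and over all wells (94.9th).

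Chromatin, imprinted, housekeeping and ribosomal protein lists lay within the range of random lists with division by the gene total, although single members stood out. Dnmt3l, a cofactor of DNA methylation (4.38), Tet1, a 5-methylcytosine oxidase (4.03), Hmgb1 (3.29) and Jarid2 (2.37) were above technical noise, and Dnmt3l lost its call without wells C03, H03 and H12. Among imprinted genes, the cell cycle inhibitor gene Cdkn1c (5.89), Phlda2 (5.24) and Grb10 (2.38) were above. The housekeeping genes Hsp90ab1 (1.01) and Ppia (1.38) were close to the spike-ins, while Actg1 (7.29), Eef1a1 (4.79) and Rplp0 (4.09) were above. Unique reads gave 0.464% of the molecules of Actg1, 33.1% for Rplp0, 45.3% for Eef1a1, 10.3% for Ppia and 4.48% for Hmgb1, so these are uncertain. List medians were 1.47, 1.42, 1.89 and 1.63, at the 65.7th, 84.5th, 86.5th and 14.6th percentiles. The housekeeping list moved to the 99.5th with the spike-in total, 99.9th with none, 97.8th with scran and 99.6th over all wells, and the imprinted list to the 100th with none and over all wells. The ribosomal protein list moved to a percentile of 2.1 with scran. Of 94 ribosomal protein genes 18 were above, with Rps4x at 10.1 and 3.66% unique reads. Mitochondrially encoded genes gave 19 of 34, with a median of 3.53 above all random lists and examples in mt-Rnr1 (7.21) and mt-Atp6 (7.07, 0% unique and so uncertain).

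With division by the gene total, members of most lists correlated more from cell to cell than random matched genes, though weakly in several. Naive-state genes had a median pairwise Spearman rho of 0.274, while the middle 95% of random matched lists ran from -0.0296 to 0.06804. Mitochondrial genes had 0.197, G2 and M phase genes 0.193, cholesterol synthesis genes 0.173, G1 and S phase genes 0.154 and primed-state genes 0.139, all above every random list. Core pluripotency genes had 0.0671 at the 98.8th percentile. Mesendoderm genes had 0.206, primitive endoderm genes 0.1999, trophectoderm genes 0.177, feeder genes 0.127, p53 genes 0.1099, immediate early and stress genes 0.0734, imprinted genes 0.0722, glycolysis genes 0.0569 and ribosomal protein genes 0.0503, at the 98.5th percentile or above. The 2-cell-like list had 0.359 over 4 Zscan4 genes, and 0.265 without wells C03, H03 and H12. These genes had a molecule in 3 to 10 of the cells, with most molecules in well A08. Of their molecules, 10% for Zscan4f and none for the other 3 came from unique reads, so the value is uncertain. Chromatin genes (0.0163, 71.9th percentile) and housekeeping genes (0.0168, 55.8th percentile) did not stand apart with division by the gene total, but chromatin genes reached the 99.9th percentile after thinning and housekeeping genes the 97.8th with no normalization. In all, 17 of 19 lists lay in the highest 2.5% of random lists. This number was 11 after division by the spike-in total, 8 with no normalization and 9 over all wells. The naive, G1 and S, G2 and M, cholesterol and ribosomal protein lists stayed in it in all alternatives run, as did the 2-cell-like list where it was measured. Each of the other lists left it in at least 1. The primitive endoderm list turned to a rho of -0.0328 after thinning (33.4th percentile) and had 0.0625 with scran (77.4th). Over all wells the mitochondrial list was at the 16.8th percentile, the primed list at the 89.8th, the immediate early list at the 70.4th and the imprinted list at a percentile of 3.8. With no normalization the core pluripotency list was at the 51.3th, glycolysis at the 48.1th, feeder genes at the 56.6th, p53 genes at the 85.3th, trophectoderm genes at the 90.5th and mesendoderm genes at the 97.1th.

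**Figure D4:**
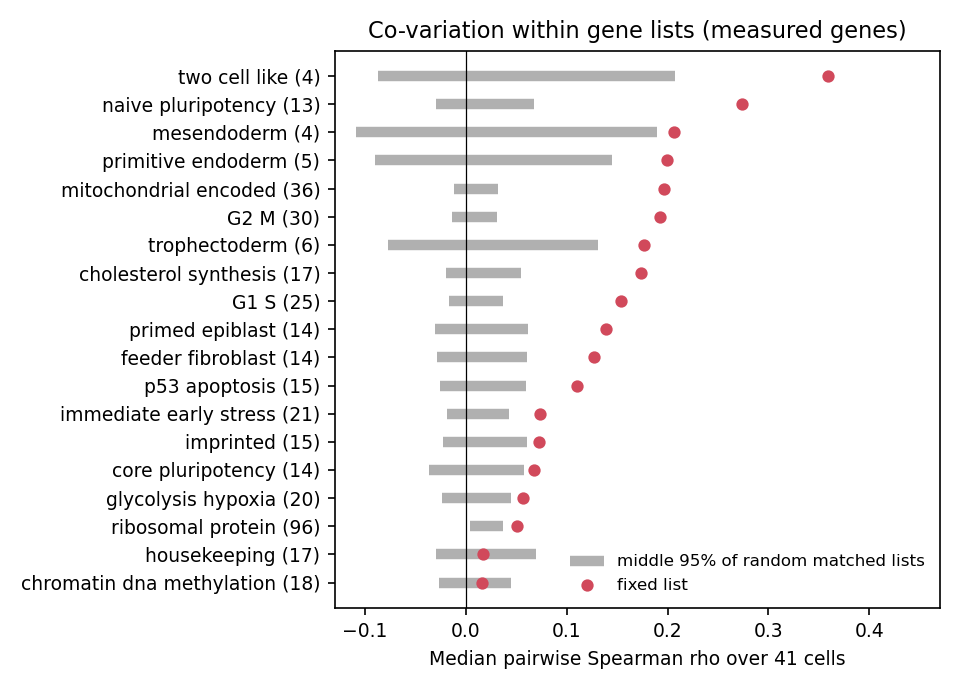
For each gene list, with the number of measured genes in brackets, the red point is the median pairwise Spearman rho over the ES cell-like wells and the grey bar is the middle 95% of 10000 random lists matched on mean level. Naive pluripotency genes reach 0.274, and housekeeping and chromatin genes lie inside their grey bars.

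Among gene pairs, the naive factor genes Esrrb and Zfp42 rose together and ran against Dnmt3b. Esrrb and Zfp42 had Pearson's r of 0.749 and Spearman's rho of 0.704, and r of 0.7396 without the 2 cells farthest from the median of the first gene. Esrrb and Dnmt3b had r of -0.505 and rho of -0.526 (r of -0.525 without 2 cells), and Zfp42 and Dnmt3b had r of -0.4503 and rho of -0.429 (r of -0.401). These lay at the 99.99th, 0.09th and 0.54th percentiles of random pairs matched on mean level. Nanog went less with the same genes, with r of 0.3003 and rho of 0.337 with Zfp42 (r of 0.3495) at the 95.5th percentile. With Esrrb it had r of 0.102 and rho of 0.217 (68.8th percentile). With Dnmt3b it had r of -0.114 and rho of -0.0713 (25.3th), so both pairs lay within the range of random pairs. Pou5f1 and Sox2 had r of 0.129 and rho of 0.0256 (r of 0.0743) at the 74.97th.

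Of 27 pairs measured out of 30 fixed ones, 8 lay in the highest 2.5% of random pairs and 2 in the lowest. Besides Esrrb and Zfp42, the high pairs were the keratins Krt8 and Krt18 (r of 0.568, rho of 0.406, r of 0.433 without 2 cells, 99.8th percentile), Lefty1 and Lefty2 (0.543, 0.473, 0.4597, 99.8th), Jun and Fos (0.474, 0.4305, 0.386, 99.7th), Fos and Egr1 (0.472, 0.417, 0.319, 99.3th), the proliferation genes Top2a and Mki67 (0.441, 0.519, 0.541, 99.6th), Zfp42 and Dppa3 (0.343, 0.332, 0.326, 98.5th), and Esrrb and Tbx3 (0.395, 0.272, 0.135, 99.3th). Unique reads gave 62.7% of Lefty2 molecules, so reads shared with a similar gene could add to its correlation with Lefty1. Without 2 cells, Esrrb and Tbx3, and Fos and Egr1, fell below the upper limits of random pairs with all cells (0.324 and 0.377). With no normalization, and over all wells, 3 pairs were that high.

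**Figure D5:**
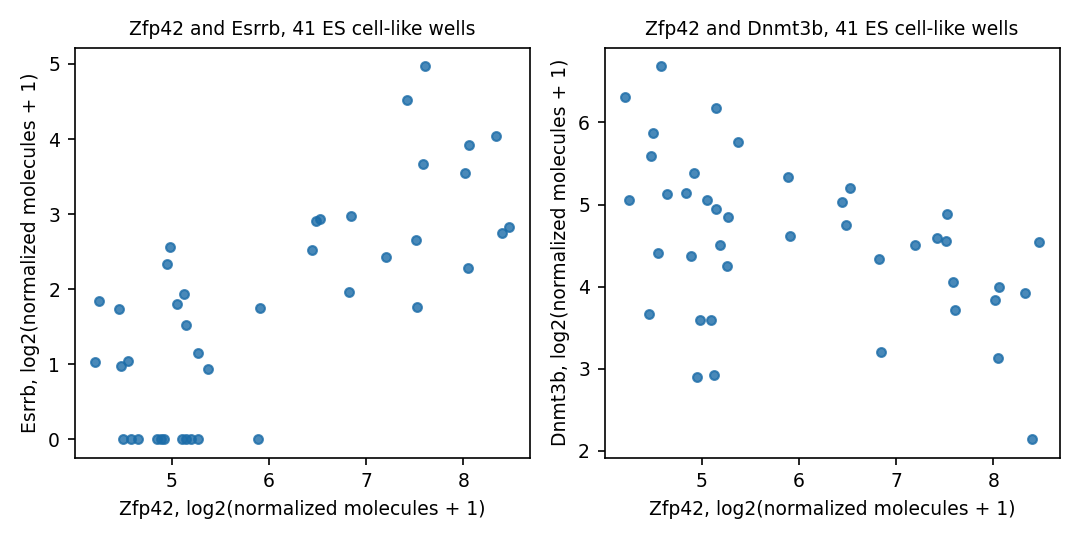
Each point is 1 of the 41 ES cell-like wells, with log2(normalized molecules + 1) of Zfp42 against that of Esrrb and of Dnmt3b. Esrrb rises with Zfp42 (Pearson's r of 0.749) and Dnmt3b falls (r of -0.4503).

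The spread of gene molecules between ES cell-like wells came mainly from 3 wells. They held a median of 98750 gene molecules with a CV of 71.2%, and 12.7 gene molecules per spike-in molecule with a CV of 16.7%. Without wells C03, H03 and H12, the CV of gene molecules was 18.5% and that of spike-ins 7.64%, and per spike-in molecule the CV was 14.9%. Over all ES cell-like wells, log2 gene and spike-in totals had Pearson's r of 0.946 and Spearman's rho of 0.635 (r of 0.802 without 2 wells), and without these 3 wells r was 0.628.

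Repeat elements gave a median of 94353 molecules per ES cell-like well, close to the number from genes. Short interspersed elements of the B1 to B4 groups, copied from small polymerase III transcripts, made up a median of 53.5% of repeat molecules. Among them B2_Mm1a had a mean of 23864 molecules and a noise ratio of 26.9. L1 elements, long retrotransposons, made up 7.68%, IAP endogenous retroviruses 0.155% and MERVL 0.0217%. Above technical noise were 196 of 681 repeat types, including 32 of 97 L1 types, 15 of 17 B1 to B4 types, 6 of 17 IAP types and 2 of 3 MERVL types. Repeat counts were divided by the cell's total of gene molecules. A difference between wells in all repeat RNA alike would raise the ratios of many types together. Well D07, for example, held 129248 repeat and 91269 gene molecules, and A03 38761 and 74154. After thinning, 118 repeat types were above technical noise, and the same cells gave 174 without thinning. Over all wells the number was 361. MT2_Mm, the long terminal repeat of MERVL, had a ratio of 139.7 that fell to 11.1 without its highest cell. The small RNA 4.5SRNA (81.05), the satellite GSAT_MM (76.5) and BC1_Mm (68.1) came next.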

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

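Leaving out wells C03, H03 and H12, keeping only the wells of the higher range, fitting spike-ins over ES cell-like wells, grouping L1 and B1 to B4 repeats by how their names begin, the cells left by thinning with division by the gene total and totals without mitochondrial genes and Rn45s were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because each column belongs to a cell and both its library forms, so the planned single against amplified alternatives (replicate block, DESeq2, no filter) were not run. Genes above technical noise numbered 308. They were 622 with the spike-in total, 1197 with no normalization and 120 after thinning, of which 290, 284 and 120 were shared. A ratio of at least 1.5 gave 1020, of at least 3 93, all cells only 975 and Poisson noise 7166. The cells left by thinning gave 295 without thinning. With scran they were 335 (274 shared), over all wells 366 (150 shared) and without the 3 wells 304 (281 shared). Of 68 named genes above technical noise, 28 lost the call after thinning, 25 over all wells and 6 without the 3 wells. Lists with high co-variation numbered 17, and 11 with the spike-in total, 8 with no normalization and 9 over all wells. High gene pairs numbered 8, and 3 with no normalization and 3 over all wells. Repeat types above technical noise numbered 196, 118 after thinning (174 in the same cells without thinning) and 361 over all wells. The CV of gene molecules went from 71.2% to 16.7% per spike-in and 18.5% without the 3 wells. The ES cell-like class held 37 to 51 wells, the spike-in coefficient was 2.52 to 3.49, and 9 to 11 lists had high noise against 10. The members changed too. The cause was not tested.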

Other observations

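All that follows was chosen after the data were seen, except that the tests of cytosolic against endoplasmic reticulum mRNAs and of transcript length as part of the cause were set before their result was seen. Well A08 of the ES cell-like class carried RNAs known from the 2-cell embryo. It held 58 molecules of Zscan4 genes and other fixed markers of this state (exact Poisson 95% interval 44.04 to 74.98, counting error only), and the other 40 ES cell-like wells had a median of 0 and at most 15. MERVL and its repeat MT2_Mm gave 454 molecules there, or 84.1 per 10000 gene molecules, against at most 14.2 in the other wells. Zscan4f had 21 molecules and Zscan4b 17, and Mreg, a melanosome transport gene, had 112. Unique reads gave 10% of Zscan4f and 0% of Zscan4b molecules, so the copies were not separated. Spry2, an inhibitor of growth factor signalling, had 26 molecules, all from unique reads. A08 also stood apart in other values, with 53975 gene molecules, the lowest number per spike-in molecule of the class (8.01), 15.8% mitochondrial RNA and the highest share of Rn45s (5.52%, against a median of 2.3001%).

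Zfp42 rose together with Tdh, the threonine dehydrogenase gene of mouse ES cells, with a Spearman rho of 0.831. It was the highest among 3161 genes with a mean of at least 5 molecules, followed by Dhx16 (0.7599), Mybl2 (0.726), the glutathione peroxidase gene Gpx4 (0.725), 8430410A17Rik (0.713) and the autophagy gene Gabarapl2 (0.6997). When Zfp42 values were shuffled over cells 1000 times, the highest rho with any gene had a median of 0.526 and reached at most 0.678, which these 6 genes exceeded. The lowest rho, of the tight junction gene Cldn7 (-0.737), was below the median of the lowest rho of a shuffle (-0.523). It did not pass the lowest of any shuffle (-0.746). Every ES cell-like well had at least 3 Zfp42 molecules.

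The wells of cluster 2 held 17.6% of the non-mitochondrial gene molecules of ES cell-like wells, 66.6% of the mitochondrial and 76.7% of the spike-in molecules. Loss of all RNA alike after lysis is argued against, since the share of spike-ins left was 4.35 times that of non-mitochondrial gene molecules. Spike-ins were added at lysis, so they cannot show RNA lost before it. Per well, 24 mRNAs translated in the cytosol changed by a median log2 of -3.04, 27 bound to the endoplasmic reticulum by -2.24 and 6 nuclear RNAs by -1.53. Among the nuclear RNAs, the abundant Malat1 changed by -2.14, near the reticulum median, and Meg3 by -0.985. Tsix and Mirg had means of only 1.51 and 1.41 molecules in ES cell-like wells. All tested genes outside the mitochondrial genome had a median of -2.48, and the reticulum list lay at the 63.8th percentile of them. The reticulum list thus lay 0.80 above the cytosolic one, as loss of soluble cytoplasm from damaged cells may produce. Genes matched on length and mean differed by 0.37, so retention of long transcripts stays open as part of the cause, but not as the whole, because the reticulum list lay at the 99.8th percentile of lists matched on length. The cytosolic list lay at the 18.7th percentile of its matched lists, whose median was -2.99. Its fall was thus not beyond that of matched genes, which leaves loss of cytoplasm unsettled. Free RNA or debris in chambers without an intact cell was not tested, and no biological explanation was tested.

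Spike-in variance was about 3 times the mean at low levels. Differences in efficiency between wells are argued against, because they would bring variance over mean close to 1 there, and its median was 2.72 for means of 0.1 to 1. The 3 wells with outlying spike-in totals are not the cause, as the coefficient was 3.03 without them. Where under 0.3 molecules were expected, 36 of 116 non-zero counts were 2 or more (31.03%), 4.49 times the 6.91% of a Poisson count. Variance above the mean alone gives such an excess, so this value decides nothing, and whether one original molecule was counted several times stays open, with no biological explanation tested.

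Wells C03 and H03 held 5.21 and 7.96 times the median number of spike-in molecules. More spike-in solution with proportional counting is argued against, since it would raise each spike-in alike. The fold rise of the 4 most abundant was 0.6405 times that of the 20 middle ones in C03 and 0.593 times in H03. Whether counting stays proportional at such levels was not tested, so more solution is not excluded. Gene molecules rose too, with 8.76 and 10.3 per spike-in molecule, against 8.01 to 17.6 in the other ES cell-like wells. The lowest of these was A08 and the next 9.72, so C03 lay inside the range only because of A08. C03 and H03 had 11137 and 12286 detected genes, against at most 7569 in the other ES cell-like wells. Mitochondrial RNA was 16.3% and 15.1%, against a class median of 10.4%. Their normalized levels were close for Dppa5a (650 and 663), Zfp42 (91.3 and 86.1) and Krt8 (52.3 and 49.2). Those of Lefty1 were less so (34.97 and 47.8). Class medians were 1084.7 for Dppa5a, 37.6 for Zfp42, 14.5 for Krt8 and 21.7 for Lefty1. Both wells thus lay on the same side of the class median for each of these genes. Counting depth or counting errors that reach spike-ins and genes alike stay open, and whether either well held RNA of several cells was not tested. Both counted as cells in the results above. No biological explanation was tested.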
